A study of Mus musculus with 24 samples.

How the data were processed

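The libraries measured mRNA in mouse brain cell types, in isolated microglia, in embryonic cortex and in liver, as listed in the results. The authors deposited a whole-number count per gene for each library, without normalisation, and these counts were used as deposited. Per the submitters' processing notes, cutadapt and Novoalign were used for PAPERCLIP, STAR for RNA-seq, and the mouse build was mm10; versions are not stated. Per the labels' protocols, PAPERCLIP crosslinks RNA to the poly(A)-binding protein and its linkers carry a 7-base random barcode, microglia were taken from 2 brains per tube with CD11b beads, microglial RNA-seq selected poly(A) RNA and the knockout cortex was ribosome-depleted. Whether barcoded duplicates were collapsed, how reads were assigned to genes and whether strand was used are not given in the sources used here. Counts of overlapping genes, and of families with near-identical copies such as haemoglobins, Hspa1a and Hspa1b, or H2-K1 and H2-D1, are therefore uncertain.

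PAPERCLIP tables held 23871 genes by symbol and RNA-seq listed 47069 Ensembl identifiers, of which 46488 matched a gene name table. For the tests that join both assays by symbol, 23091 genes were shared after 707 older symbols were updated. Positions come from a GRCm38 gene table, the assembly that mm10 names. Labels call the knockout libraries biological replicates and say no such thing of the others, so p-values measure the spread between libraries, which may in part be technical. Replicate pairs were compared with a chi-square test of their counts over genes with at least 10 counts; chi-square per degree of freedom was 2.10 to 76.9, so no pair differed by sampling noise alone, and the untreated Cx3cr1 pair had the lowest correlation, 0.674.

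Groups were taken from the sample titles. Tests used edgeR 4.0.16 quasi-likelihood fits (R 4.3.3) with filterByExpr, TMM scaling and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05; every adjusted p given for a gene comes from this test unless another tool is named. The 3 cell type comparisons came from a single fit of 8 untreated libraries, PBS against untreated from a fit that kept the LPS libraries for the spread, and each LPS comparison from its own 6 libraries. The difference in LPS response came from 12 libraries as 4 group means. Normalised CPM use TMM-scaled totals; plain CPM use the library total as it stands. SE is that of the log2 change, taken from the F statistic. Where groups on both sides of a contrast had no count, the change is not determined and its p lies near 1, which is no evidence of equal levels.

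Before the data were examined, 37 gene lists, the alternatives and the rule for named genes were fixed. The lists hold 546 genes: cell type markers, neuronal gene groups, RNA-processing and signalling genes, metabolic genes and immune gene groups. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one, with adjustment over the lists of a comparison, and the adjusted p of a list comes from that test. The rule names the driver genes, Araf, Ptbp1, Ptbp2 and Pabpc1; the 6 largest changes in each direction among genes past the threshold with an average log2 CPM of at least 3 and groups that do not overlap, leaving out predicted and mitochondrial genes; the 3 members with the smallest p of each list in its main direction and 1 in the other; and the top genes and list members of liver and knockout cortex. A part of these genes is given. For genes named as changed, values of the groups compared did not overlap unless stated. Chance alone gives this for 10% of genes with 3 against 3, and for more with 2 against 2 or 3 against 2. Where a group had no count, the fold is a bound against 3 counts over the group. Clopper-Pearson intervals, bounds and floors cover counting error only. The 95% intervals of Apoe come from the SE and the spread between libraries.

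Pairing was checked from the correlation of deviations from group means over genes with at least 20 CPM. In LPS against PBS PAPERCLIP, replicates of the same number correlated at 0.126, 0.257 and 0.199, with every other pairing below 0, so the numbers were taken to pair these libraries. The check used the data alone, since labels state no shared litter or day.

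Alternatives were other scalings (RLE and total counts), DESeq2 1.42.0, no filter, a filter at 5 CPM, a replicate block, a batch term from file-name prefixes, a fit of all 14 tagged brain libraries, leaving out replicate 3 of both LPS and PBS, and leaving out each library. After the data were seen, libraries thinned to the shallowest total (133456 counts in the untreated fit and 266330 in the LPS fit) and leave-one-out of the knockout mean were added. Simulated counts, with 200 genes changed by known folds, tested each fit. They took the real depths, the mean of each gene over all libraries of an assay, and a single spread shared by all genes. The shares recovered therefore do not cover genes or groups that varied more than this. The share of 4-fold higher genes recovered was 98.0% for Camk2a against Gad2, 100% for Gfap against neuronal, 80.9% for Cx3cr1 against cortical, 84% for PBS against untreated, 100% for LPS in PAPERCLIP, 100% for LPS in RNA-seq and 52% for the difference in response. For 4-fold lower genes it was 89.1%, 78.6%, 37.8%, 68.1%, 95.2%, 100% and 53.1%. Because 37.8% missed the 40% first required, the requirement became 90% of 4-fold changes in genes with at least 30 expected counts. The difference in response was left out of it and recovered 57.5% of higher and 63.6% of lower genes there. Summaries used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.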

Results

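The series holds 24 libraries of mouse RNA. In cTag-PAPERCLIP, a Cre recombinase switches on a GFP-tagged poly(A)-binding protein in a chosen cell type, and mRNA bound to it is recovered from whole tissue with anti-GFP antibodies, so no cell sorting is needed. Tagged cortex gave 2 libraries each from the Gfap-Cre, Gad2-Cre and Camk2a-Cre lines. Tagged whole brain of the Cx3cr1-Cre line gave 2 untreated libraries, 3 after PBS and 3 after bacterial lipopolysaccharide (LPS), which triggers innate immunity. A single PAPERCLIP library came from liver, labelled CL57/B6J with no Cre line or tag named. RNA-seq covered microglia isolated with CD11b beads from wild-type adults, 3 libraries after PBS and 3 after 1 mg/kg LPS given on 4 days, and Ptbp2-knockout cortex of E18.5 embryos in 3 libraries. The series title names alternative polyadenylation and an Araf isoform shift in activated microglia, but values per gene do not separate polyadenylation sites, and sites were not analysed here.

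Depth differed between groups. Library totals were 800886 and 1749778 counts for Gfap, 630475 and 950497 for Gad2, and 2005627 and 1833177 for Camk2a. The Cx3cr1 libraries held 154959 and 133456 counts untreated, 275894, 266330 and 337770 after PBS, and 1041245, 679115 and 848317 after LPS. Liver held 115734 counts. Microglial RNA-seq held 2019896, 1254076 and 1751725 counts after PBS and 1533910, 2133407 and 1250170 after LPS, and the knockout cortex held 27141384, 27415288 and 19446610.

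Each driver line was richest in the genes of its own cell type. Microglial marker genes took 7.43% to 8.99% of counts in the Cx3cr1 libraries and 0.00563% to 0.0209% in the cortical ones. Astrocyte genes took 4.61% and 3.88% in the Gfap libraries, inhibitory neuron genes 1.86% and 1.47% in the Gad2 libraries, and excitatory neuron genes 1.05% and 0.995% in the Camk2a libraries. Oligodendrocyte genes differed between the Gfap libraries, at 0.129% and 0.983%. In PBS replicate 3, pan-neuronal genes took 0.424% of counts and hepatocyte genes 0.307%, whereas the other 5 PBS and LPS libraries held at most 0.083% and 0.0718%. The liver gene Alb reached 1294 CPM in that library and at most 19.1 CPM in every other brain PAPERCLIP library.

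**Figure D1:**
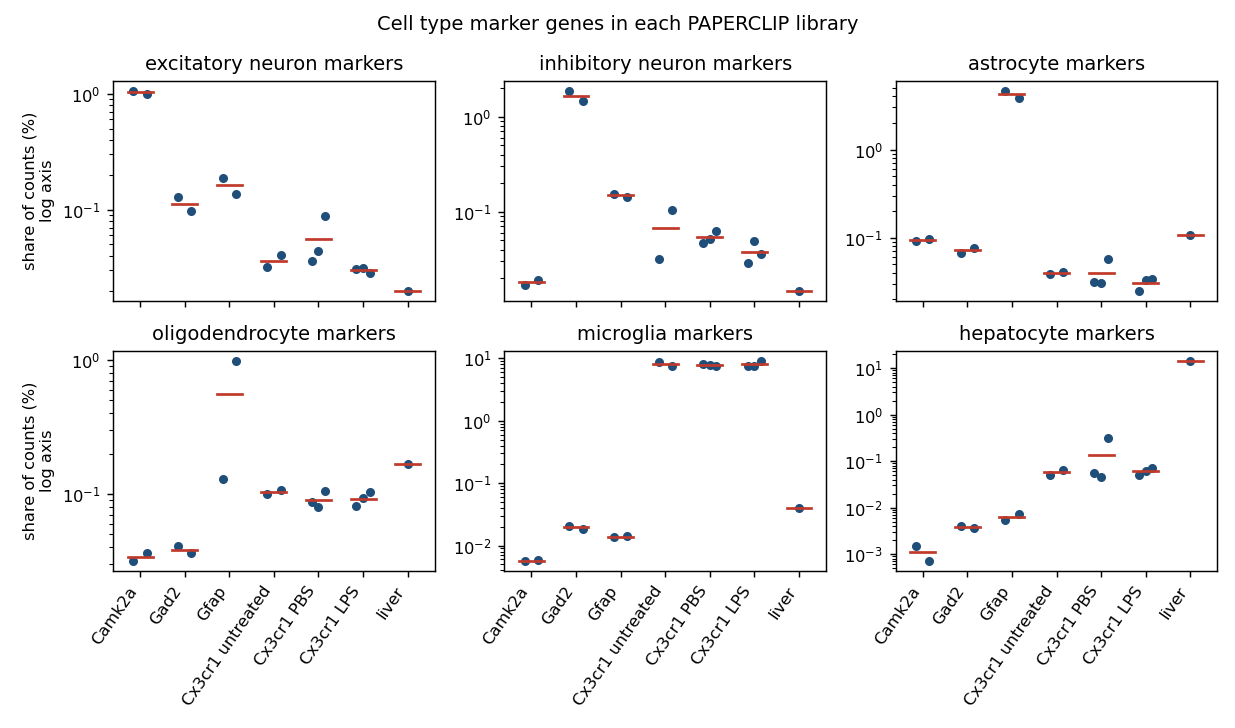
Share of all counts (percent, log axis) taken by 6 marker gene lists in the 7 PAPERCLIP groups; each blue point is a library and each red line a group mean. Microglial genes took 7.43% to 8.99% in the Cx3cr1 libraries, and hepatocyte genes took 13.99% in liver.

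The comparison of Camk2a with Gad2 libraries set excitatory against inhibitory cortical neurons. Genes of excitatory projection neurons were far higher in the Camk2a libraries. The transcription factor gene Neurod6 averaged 330 ± 15.3 against 3.79 ± 1.17 normalised CPM (SD, n = 2 libraries per group; log2 difference 6.46, SE 0.43, adjusted p = 6.02e-09), and Tbr1, a cortical layer regulator, differed by 5.11 (SE 0.35). Camk2a itself, a synaptic kinase, was higher by 2.42 (SE 0.38, adjusted p = 9.7e-05). The GABA-synthesising enzymes Gad1 and Gad2 differed by −7.61 (SE 0.35) and −5.84 (SE 0.33), and the vesicular GABA transporter Slc32a1 by −7.37 (SE 0.38). Dlx5, a transcription factor of developing interneurons, had no count in Camk2a libraries and was at least 58.2-fold lower there than in Gad2 libraries (42.9 ± 2.01 normalised CPM). Of 9421 genes tested, 1097 were higher and 904 lower in the Camk2a libraries (2001 in all). That number was 1209, 1026, 1127 and 1180 without Gad2 replicate 1, Gad2 replicate 2, Camk2a replicate 1 and Camk2a replicate 2, each of which left a group with 1 library.

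All 17 inhibitory neuron genes were lower in Camk2a libraries, also when adjusted over the list alone (adjusted p = 4.33e-33, and adjusted p = 0.00824 with an estimated correlation). Of 18 excitatory neuron genes, 16 were higher (16 higher and 1 lower adjusted over the list alone; adjusted p = 1.26e-16, and adjusted p = 0.11 with an estimated correlation). Neuropeptide genes split as 2 higher and 10 lower of 13, with the same counts adjusted over the list alone (adjusted p = 1.61e-11, and adjusted p = 0.0547 with an estimated correlation). Vip and Tac1, interneuron peptides, differed by −7.27 (SE 0.36) and −7.12 (SE 0.37), while Cck, cholecystokinin, was higher in the Camk2a libraries by 2.64 (SE 0.33). Pvalb, a calcium buffer of fast-spiking interneurons, and Kcnc1, a fast potassium channel, were lower in them, by −5.77 (SE 0.29) and −3.55 (SE 0.27). The potassium channel list as a whole did not pass (adjusted p = 0.601), with a median of 0.09 above 0 and a mean of −0.45 and test direction below 0. Splicing regulators were higher for 10 and lower for 4 of 22 (11 and 4 adjusted over the list alone; adjusted p = 0.0497, and adjusted p = 0.672 with an estimated correlation). That call was lost without Gad2 replicate 1 (adjusted p = 0.0519), Gad2 replicate 2 (0.199) or Camk2a replicate 1 (0.0702), and with either other scaling (0.0558 and 0.0586). Among its members, the neuronal RNA-binding proteins Rbfox3 and Elavl2 differed by 1.63 (SE 0.25) and −1.88 (SE 0.24).

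Microglial genes were low in both groups but lower in the Camk2a libraries, with 6 of 22 passing (9 adjusted over the list alone; adjusted p = 0.00156, and adjusted p = 0.11 with an estimated correlation). With all libraries thinned to the shallowest, a setting chosen after seeing the data, that adjusted p was 0.727. Of 12 ionotropic glutamate receptor genes, the AMPA receptor subunit Gria2 was higher (1.30, SE 0.25) and the NMDA subunit Grin3a lower (−3.23, SE 0.31) in the Camk2a libraries, and the list did not pass (adjusted p = 0.741), with a median of 0.26 and a mean of −0.21. Activity-regulated genes went both ways, with Egr3 at 4.34 (SE 0.46) and Fos at −1.74 (SE 0.25), and that list did not pass either (adjusted p = 0.843).

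The Gfap libraries were compared with the mean of both neuronal groups to contrast astrocytes with neurons. The X-inactivation gene Xist had no count in the Gfap libraries and averaged 32.5 and 31.2 normalised CPM in the Camk2a and Gad2 libraries. The sex of the mice may therefore differ too. Gfap, the astrocyte intermediate filament, averaged 619 ± 31 normalised CPM against 1.73 ± 0.391 in Camk2a and 1.54 ± 2.17 in Gad2 libraries (SD, n = 2 each; log2 difference 8.63, SE 0.33, adjusted p = 3.63e-13). Without Gad2 replicate 1 and Gad2 replicate 2 the difference was 10.38 and 7.98. The water channel Aqp4 was higher by 8.08 (SE 0.29) and the glutamate transporter Slc1a3 by 8.04 (SE 0.29). Of 9421 genes, 2945 were higher and 2757 lower (5702 in all). With total counts as the only scaling, the split was 2523 higher and 3215 lower and the median of all genes moved from 0 to −0.21. All 19 astrocyte genes were higher, also adjusted over the list alone (adjusted p = 6.1e-37, and adjusted p = 0.0215 with an estimated correlation).

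Neuronal gene groups were lower in the Gfap libraries. All 16 pan-neuronal genes were lower, with the glycolytic enzyme Eno2 at −3.69 (SE 0.30), also adjusted over the list alone (adjusted p = 3.6e-09, and adjusted p = 0.28 with an estimated correlation). Of 15 synaptic vesicle genes 14 were lower, with the same count adjusted over the list alone (adjusted p = 3.16e-07, and adjusted p = 0.28 with an estimated correlation), with Vamp1, a vesicle fusion protein, at −5.59 (SE 0.31). All 11 potassium channel genes were lower, also adjusted over the list alone (adjusted p = 1.37e-05, and adjusted p = 0.28 with an estimated correlation), with Kcnc2 at −5.15 (SE 0.40). Neuropeptide genes were lower for 11 of 13 (12 adjusted over the list alone; adjusted p = 0.000107, and adjusted p = 0.212 with an estimated correlation), and the enkephalin precursor Penk differed by −4.38 (SE 0.34). Receptor genes showed astrocyte and neuronal members. The GABA-A subunit Gabrg1 was higher by 5.04 (SE 0.22), in a list of 10 with 2 higher and 8 lower, the same adjusted over the list alone (adjusted p = 0.00354, and adjusted p = 0.407 with an estimated correlation). The NMDA subunit Grin2c was higher by 7.00 (SE 0.26), against 9 of 12 glutamate receptor genes that were lower, the same adjusted over the list alone (adjusted p = 0.0258, and adjusted p = 0.28 with an estimated correlation).

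Splicing regulators were mostly lower in the Gfap libraries, with 2 higher and 16 lower of 22, the same adjusted over the list alone (adjusted p = 0.000362, and adjusted p = 0.395 with an estimated correlation). Qk, an RNA-binding protein of glia, was higher by 5.46 (SE 0.25) and Elavl2 lower by −4.60 (SE 0.30). Ptbp2, a splicing repressor, was higher by 1.11 (SE 0.20, adjusted p = 9.9e-05), at 112 ± 21.9 against 62.6 ± 3.63 and 44.1 ± 5.89 normalised CPM. The RAF and MAP kinase genes went both ways, 6 higher and 5 lower of 16, the same adjusted over the list alone (adjusted p = 0.771), with the GTPase Nras at 2.00 (SE 0.19). All 9 oligodendrocyte genes were higher, also adjusted over the list alone (adjusted p = 0.0071, and adjusted p = 0.548 with an estimated correlation). Part of their size came from Gfap replicate 2, with 0.983% of its counts in these genes. Without it the myelin genes Cnp, Mal and Cldn11 went from 5.07 (SE 0.37), 5.75 (SE 0.55) and 5.14 (SE 0.52) to 4.12, 3.19 and 2.72. Without Gfap replicate 1, Mal and Cldn11 were at 6.58 and 5.96. Olig1 and Olig2, markers of oligodendrocyte precursors, and the ependymal marker Tmem212 were also higher in the Gfap libraries.

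Untreated Cx3cr1 libraries were compared with the mean of the 3 cortical groups to contrast microglia with the other cell types. The purinergic receptor P2ry12, a marker of resting microglia, averaged 3835 ± 203 normalised CPM against 0.992 ± 0.72 in Camk2a, 7.24 ± 3.71 in Gad2 and 16.3 ± 1.4 in Gfap libraries (SD, n = 2 each; log2 difference 9.53, SE 0.27, adjusted p = 5.23e-15). The fractalkine receptor Cx3cr1 differed by 11.34 (SE 0.37) and the TGF-beta receptor Tgfbr1 by 8.53 (SE 0.24). Selplg, a selectin ligand, and Ly86, a receptor partner in LPS sensing, had no count in any cortical library and were at least 5333-fold and 7034-fold higher. Of 9421 genes, 2051 were higher and 2636 lower (4687 in all), with a median of all genes of −0.48 (−0.90 without untreated replicate 1 and −0.22 with libraries thinned to the shallowest). Microglial genes took 7.43% to 8.99% of counts under every file-name prefix of the Cx3cr1 libraries, so a batch behind 1 prefix does not account for them. The comparison also set whole brain against cortex, so cell type and tissue cannot be told apart for any gene. For genes other than the microglial ones, batch cannot be told apart from them either. The sex of the mice may differ too, since Xist had no count in the untreated Cx3cr1 and Gfap libraries but had counts in the Camk2a and Gad2 groups.

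All 22 microglial genes were higher in the Cx3cr1 libraries, also adjusted over the list alone (adjusted p = 3.16e-27, and adjusted p = 0.0537 with an estimated correlation). Antigen presentation genes were higher for 13 of 13, the same adjusted over the list alone (adjusted p = 1.68e-13, and adjusted p = 0.147 with an estimated correlation), and H2-Ab1, an MHC class II chain, differed by 11.46 (SE 0.33). Disease-associated microglia genes were higher for 13 of 16 (15 adjusted over the list alone; adjusted p = 5.47e-11, and adjusted p = 0.0537 with an estimated correlation), with the lysosomal protein gene Cd68 at 9.12 (SE 0.28). All 8 monocyte and border macrophage genes were also higher, the same adjusted over the list alone (adjusted p = 6.21e-08, and adjusted p = 0.219 with an estimated correlation), among them F13a1, at least 618-fold higher. Of 9 NF-kB and acute-phase genes 8 were higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.000397, and adjusted p = 0.0967 with an estimated correlation; 0.149 with libraries thinned to the shallowest), with the transcription factor subunit Nfkb1 at 3.30 (SE 0.24).

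Neuronal, astrocyte and sterol genes were lower in the Cx3cr1 libraries. Pan-neuronal genes were lower for 15 of 16, the same adjusted over the list alone (adjusted p = 6.54e-07, and adjusted p = 0.249 with an estimated correlation), and the synaptic protein Snap25 still averaged 350 ± 38.8 normalised CPM there, against 7030 ± 566 in Camk2a libraries. Astrocyte genes were lower for 11 of 19, the same adjusted over the list alone (adjusted p = 0.00351, and adjusted p = 0.219 with an estimated correlation), with the glutamate transporter Slc1a2 at −4.27 (SE 0.42). Cholesterol synthesis genes were lower for 11 of 15 (12 adjusted over the list alone; adjusted p = 0.00286, and adjusted p = 0.219 with an estimated correlation; 0.0584 without untreated replicate 1). Sqle, a sterol synthesis enzyme, had no count in the Cx3cr1 libraries and was at least 33.1-fold lower. The hexokinase Hk2 was higher by 6.90 (SE 0.80) and the glycolytic enzyme Tpi1 lower by −2.74 (SE 0.31), in a glycolysis list that did not pass (adjusted p = 0.1). The poly(A) polymerase Papola was higher by 2.78 (SE 0.20), whereas the list of 3' end processing factors went both ways, 3 higher and 5 lower of 16, the same adjusted over the list alone (adjusted p = 0.898), with a median of −0.53 and a mean of 0.21. In the RAF and MAP kinase list, Dusp6, a phosphatase acting on ERK, was higher by 3.92 (SE 0.22) and the pathway inhibitor Spred1 lower by −1.84 (SE 0.29). That list had 5 higher and 3 lower of 16, the same adjusted over the list alone (adjusted p = 0.658), with a median of −0.01 and a mean of 0.15. Ptbp2 was lower by −1.64 (SE 0.49, adjusted p = 0.00957; 0.296 with libraries thinned to the shallowest). Pabpc1, the gene of the main cytoplasmic poly(A)-binding protein, was higher by 8.21 (SE 0.68) but read 51.6 and 884 CPM in the untreated libraries. The Camk2a and Gad2 libraries held only 9 and 1 counts of it (2.22 ± 0.404 and 0.493 ± 0.697 normalised CPM). The size of the Pabpc1 difference therefore rests on few cortical counts, and whether cell type lies behind it was not tested. It was 8.97 without Gad2 replicate 2, 8.97 without untreated replicate 1 and 5.17 without untreated replicate 2.

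Injected and untreated Cx3cr1 mice were compared as a check of handling, at low depth. Med13, a Mediator subunit, averaged 25.6 ± 7.56 normalised CPM after PBS (SD, n = 3) and 242 ± 39.7 untreated (n = 2; log2 difference −3.19, SE 0.36, adjusted p = 0.00218). Dock8, a regulator of immune cell migration, differed by −2.78 (SE 0.33, adjusted p = 0.00218), and by −2.18 without untreated replicate 2. Of 22 microglial identity genes 0 passed in edgeR over all genes (median −0.11, adjusted p = 0.909), in a comparison where 12% and 15.9% of simulated 2-fold higher and lower genes were recovered. Cx3cr1 differed by −0.27 (SE 0.32, adjusted p = 0.679). The homeostatic gene Tgfbr1 was lower (−1.36, SE 0.32, adjusted p = 0.0481), a call lost without untreated replicate 2 or any 1 PBS or LPS library (adjusted p = 0.0560 to 0.285) and with total counts only (0.0501). Of 5112 genes 28 were higher and 75 lower (103 in all), against 214 with DESeq2. The excess of lower genes reversed with no filter, at 169 higher and 144 lower. It stayed but was smaller in share with total counts as the only scaling (34 higher and 56 lower). The same held in a fit of all 14 tagged brain libraries (72 higher and 97 lower). The number was 3, 37 and 12 without PBS replicates 1, 2 and 3, 495 and 16 without untreated replicates 1 and 2, and 32, 41 and 68 without LPS replicates 1, 2 and 3, which share the estimate of spread. The groups also differ in file-name prefix, so injection and batch cannot be told apart.

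LPS treatment was compared with PBS in the Cx3cr1 PAPERCLIP libraries to follow microglial activation in the intact brain. The acute-phase gene Saa3 rose from 12.1 ± 11.1 to 4465 ± 1597 normalised CPM (SD, n = 3 each; log2 change 8.40, SE 0.44, adjusted p = 2.37e-07; 9.53 without PBS replicate 3). Interferon-stimulated genes rose, among them the antiviral genes Ifit3 from 43.6 ± 9.81 to 332 ± 18.4 (2.91, SE 0.24) and Ifitm3 (2.14, SE 0.21) and the transcription factor Irf7 (3.87, SE 0.39). The chemokines Ccl5 and Cxcl16 rose by 4.36 (SE 0.39) and 2.09 (SE 0.25). Of 5692 genes, 156 rose and 45 fell (201 in all). The number was 74, 111 and 97 without PBS replicates 1, 2 and 3, and 117, 163 and 167 without LPS replicates 1, 2 and 3. Of these, 12, 31, 21, 17, 29 and 27 fell, in the same order. Among the 45 genes that fell in the main fit, 16 were lower in untreated Cx3cr1 than in cortical libraries, as were 1115 of the 5692 genes tested. Replicates of the same number varied together, and with the replicate as a block 423 genes passed, 258 higher and 165 lower, including all 201. With the file-name batch as a term 317 passed, 212 higher and 105 lower. Monocyte and border macrophage genes rose for 2 of 9 (camera adjusted p = 0.21). These were Plac8 (2.68, SE 0.52, adjusted p = 0.0105) and Ms4a7 (1.30, SE 0.28, adjusted p = 0.0197), and both calls were lost when some library was left out. Changes in these libraries therefore need not be those of microglia alone.

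The list counts given here cover only members with enough counts to be tested, not whole lists. A gene scarce after PBS could enter them only through its LPS counts, so the shares that rose may be overstated. Of 16 interferon-stimulated genes 11 rose (13 adjusted over the list alone; adjusted p = 1.19e-29, and adjusted p = 0.0191 with an estimated correlation, or 0.0816 with the replicate block too). Cytokines and chemokines rose for 9 of 11 (11 adjusted over the list alone; adjusted p = 1.55e-24, and adjusted p = 0.036 with an estimated correlation, or 0.172 with the block too). NF-kB and acute-phase genes rose for 7 of 13 (10 adjusted over the list alone; adjusted p = 2.54e-20, and adjusted p = 0.0191 with an estimated correlation, or 0.0816 with the block too), with the receptor Tlr2 at 1.65 (SE 0.23) and Nfkb2 at 1.73 (SE 0.28). Cell cycle genes rose for 8 of 12 (10 adjusted over the list alone; adjusted p = 5.87e-15, and adjusted p = 0.184 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose from 9.56 ± 1.63 to 211 ± 179 normalised CPM (4.45, SE 0.70; 3.47 without LPS replicate 1). Disease-associated microglia genes rose for 4 of 17 (8 adjusted over the list alone, and 7 over all genes with the block; adjusted p = 1.93e-05, and adjusted p = 0.261 with an estimated correlation). Complement genes rose for 3 of 10, the same adjusted over the list alone (6 rising and 1 falling there with the block; adjusted p = 0.000381, and adjusted p = 0.184 with an estimated correlation).

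Antigen presentation genes went both ways after LPS, 3 rising and 4 falling of 13 (4 and 4 adjusted over the list alone; adjusted p = 0.594), with a median of 0.14 and a mean of −0.03. The MHC class I gene H2-K1 rose from 2141 ± 90.4 to 6973 ± 577 normalised CPM (1.70, SE 0.17). The class II gene H2-Ab1 fell from 864 ± 138 to 329 ± 108 (−1.39, SE 0.25, adjusted p = 0.0065; 0.0693 without PBS replicate 1). Cd209a and Mgl2, lectins of dendritic cells and some macrophages, fell with it, by 3.47 (SE 0.64, adjusted p = 0.00785) and 2.64 (SE 0.51, adjusted p = 0.0108). Their adjusted p was 0.0868 and 0.0974 without PBS replicate 1 and 0.0528 and 0.0697 without PBS replicate 2, and that of Mgl2 0.0522 without LPS replicate 1; without LPS replicate 2 the changes were −4.38 and −3.51. Homeostatic microglia genes fell for 5 of 19, or 8 with the replicate block (6 and 11 adjusted over the list alone; adjusted p = 1.46e-08, and adjusted p = 0.0787 with an estimated correlation). P2ry12 fell from 5117 ± 358 to 2709 ± 176 (−0.92, SE 0.17, adjusted p = 0.00733), but its adjusted p was 0.0742 without PBS replicate 1 and 0.105 in a fit of all 14 tagged brain libraries. These fits, and the others that left out a library, had no replicate block. With the block and all 6 libraries, the adjusted p of P2ry12, H2-Ab1, Cd209a and Mgl2 was 0.000486, 4.51e-06, 0.000505 and 0.000297. Khdrbs3, a splicing regulator, fell by 1.84 (SE 0.26, adjusted p = 0.00148), the 1 of 12 splicing regulators past the threshold, or 2 with the block (4 lower adjusted over the list alone; adjusted p = 0.00257, and adjusted p = 0.184 with an estimated correlation). Neuronal genes fell in these libraries too, as given below, and whether the splicing list, which holds neural members, followed them was not tested. The RAF and MAP kinase list had 0 of 14 past the threshold in edgeR, with 0 adjusted over the list alone (adjusted p = 0.0719), and the 3' end processing list 0 of 17, with 0 adjusted over the list alone (adjusted p = 0.135).

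Neuronal genes were lower after LPS in these libraries. No pan-neuronal gene of 8 passed over all genes in edgeR and 6 with the replicate block, all 8 passed as lower adjusted over the list alone, and the list passed (median −1.58, adjusted p = 0.00012, and adjusted p = 0.336 with an estimated correlation). Without PBS replicate 3, where these genes took 0.424% of counts, the adjusted p of the list was 0.384. Excitatory neuron genes fell for 2 of 4 (3 adjusted over the list alone; adjusted p = 0.000998, and adjusted p = 0.242 with an estimated correlation; 0.0775 without the third replicate of either group). Nrgn, a postsynaptic calmodulin-binding protein, was among them (−1.47, SE 0.31, adjusted p = 0.0168), and its adjusted p was 0.0562, 0.13, 0.0532 and 0.0515 without PBS replicate 2, PBS replicate 3, LPS replicate 1 and LPS replicate 3.

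LPS was also compared with PBS by RNA-seq of isolated microglia. Saa3 rose from 1.05 ± 1.09 to 2456 ± 454 normalised CPM (SD, n = 3 each; log2 change 10.95, SE 0.30, adjusted p = 2.57e-09; 11.81 without PBS replicate 3). The complement gene C4b rose by 3.14 (SE 0.11), Ccl5 by 6.10 (SE 0.26) and the cytokine Il1b by 3.03 (SE 0.29). The lipid carrier Apoe rose from 1600 ± 102 to 6414 ± 797 (2.00, SE 0.12, adjusted p = 1.46e-06). P2ry12 fell from 4510 ± 471 to 1576 ± 472 (−1.52, SE 0.19, adjusted p = 0.000102), Tmem119, a microglial surface protein, by 0.85 (SE 0.11) and Cx3cr1 by 0.59 (SE 0.11). Of 10267 genes 1634 rose and 1072 fell (2706 in all), against 1177 and 604 (1781 in all) with DESeq2. In edgeR, a term for replicate 3, which differed in sex from 1 and 2 in both groups, gave 1763 rising and 1323 falling. Leaving out replicate 3 of both groups gave 1995 rising and 1557 falling. Without PBS replicates 1, 2 and 3, 719, 705 and 1172 genes fell, and without LPS replicates 1, 2 and 3, 586, 669 and 1158. In these 6 fits 1259 to 1816 genes rose. With total counts as the only scaling, 1282 rose and 1641 fell, and the median of all genes moved from −0.02 to −0.13. Relative to that median, Tmem119 and Cx3cr1 fell by 0.83 and 0.57 under total counts.

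Disease-associated microglia genes rose for 18 of 20, the same adjusted over the list alone (adjusted p = 2.97e-25, and adjusted p = 0.0574 with an estimated correlation), including the integrin Itgax (2.50, SE 0.14) and the lysosomal tetraspanin Cd63 (1.37, SE 0.08). NF-kB and acute-phase genes rose for 18 of 20, the same adjusted over the list alone (adjusted p = 1.76e-16, and adjusted p = 0.0683 with an estimated correlation). Interferon-stimulated genes rose for 15 of 24 (20 adjusted over the list alone; adjusted p = 8.97e-09, and adjusted p = 0.182 with an estimated correlation), with the antiviral genes Ifit2 at 1.65 (SE 0.16) and Oasl2 at 1.62 (SE 0.19). Cytokines and chemokines rose for 11 and fell for 1 of 18 (12 and 1 adjusted over the list alone; adjusted p = 1.1e-08, and adjusted p = 0.113 with an estimated correlation), the falling member being Il6 (−2.27, SE 0.44). Cell cycle genes rose for 16 of 19, the same adjusted over the list alone (adjusted p = 8.97e-09, and adjusted p = 0.369 with an estimated correlation), with Mki67, a marker of dividing cells, at 3.38 (SE 0.39). Homeostatic microglia genes fell for 17 of 20, the same adjusted over the list alone (adjusted p = 3.62e-13, and adjusted p = 0.248 with an estimated correlation).

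MHC genes went both ways here too, with H2-K1 at 1.80 (SE 0.13), H2-D1 at 1.89 (SE 0.12) and H2-Ab1 at −0.98 (SE 0.12). Cd209a fell by 5.69 (SE 0.70; −7.53 without LPS replicate 2), Mgl2 by 3.73 (SE 0.45; −4.60 without LPS replicate 3) and Lyve1, a marker of border macrophages, by 1.57 (SE 0.33). Antigen presentation genes rose for 8 and fell for 5 of 17, the same adjusted over the list alone (adjusted p = 0.0158, and adjusted p = 0.3 with an estimated correlation; 0.101 without PBS replicate 3). Pabpc1 rose from 453 ± 24.8 to 1181 ± 49.2 normalised CPM (1.38, SE 0.09, adjusted p = 1.72e-06), while the 3' end processing factors had 2 rising and 1 falling of 21 (1 rising adjusted over the list alone; adjusted p = 0.587). Splicing regulators rose for 1 and fell for 4 of 14, the same adjusted over the list alone (adjusted p = 0.023, and adjusted p = 0.307 with an estimated correlation; 0.0783 without PBS replicate 3 and 0.0689 without the third replicate of either group). Khdrbs3 fell by 2.14 (SE 0.27). In the RAF and MAP kinase list 2 rose and 3 fell of 17, the same adjusted over the list alone (adjusted p = 0.312), with Dusp6 at −0.98 (SE 0.10).

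Markers of cells other than microglia moved with treatment in the isolated cells. Erythroid genes fell for 4 of 4, the same adjusted over the list alone (adjusted p = 1.68e-08, and adjusted p = 0.071 with an estimated correlation), and the haemoglobin gene Hbb-bs, which has near-identical copies, fell from 64.4 ± 6.55 to 6.41 ± 3.56 normalised CPM (−3.44, SE 0.28). Mural genes fell for 4 of 7, the same adjusted over the list alone (adjusted p = 0.00254, and adjusted p = 0.369 with an estimated correlation), with the pericyte receptor Pdgfrb at −2.24 (SE 0.40). Ependymal and choroid plexus genes fell for 5 of 8 (7 adjusted over the list alone; adjusted p = 0.00821, and adjusted p = 0.539 with an estimated correlation); they took 0.844%, 0.792% and 0.192% of counts in PBS libraries and 0.160%, 0.204% and 0.191% in LPS libraries. Monocyte and border macrophage genes rose for 4 and fell for 2 of 11 (4 and 3 adjusted over the list alone; adjusted p = 0.505). All 5 lymphocyte genes rose, also adjusted over the list alone (adjusted p = 9.07e-07, and adjusted p = 0.182 with an estimated correlation). Gzma, a protease of cytotoxic cells, rose from 4.87 ± 1.78 to 112 ± 37.3 normalised CPM (4.48, SE 0.32, adjusted p = 2.56e-06), and Lck, a T cell kinase, by 3.81 (SE 0.47). They rose alongside Ccl5 and the cell cycle genes. Neutrophil genes had 0 of 9 past the threshold in edgeR (0 adjusted over the list alone; adjusted p = 0.254).

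**Figure D2:**
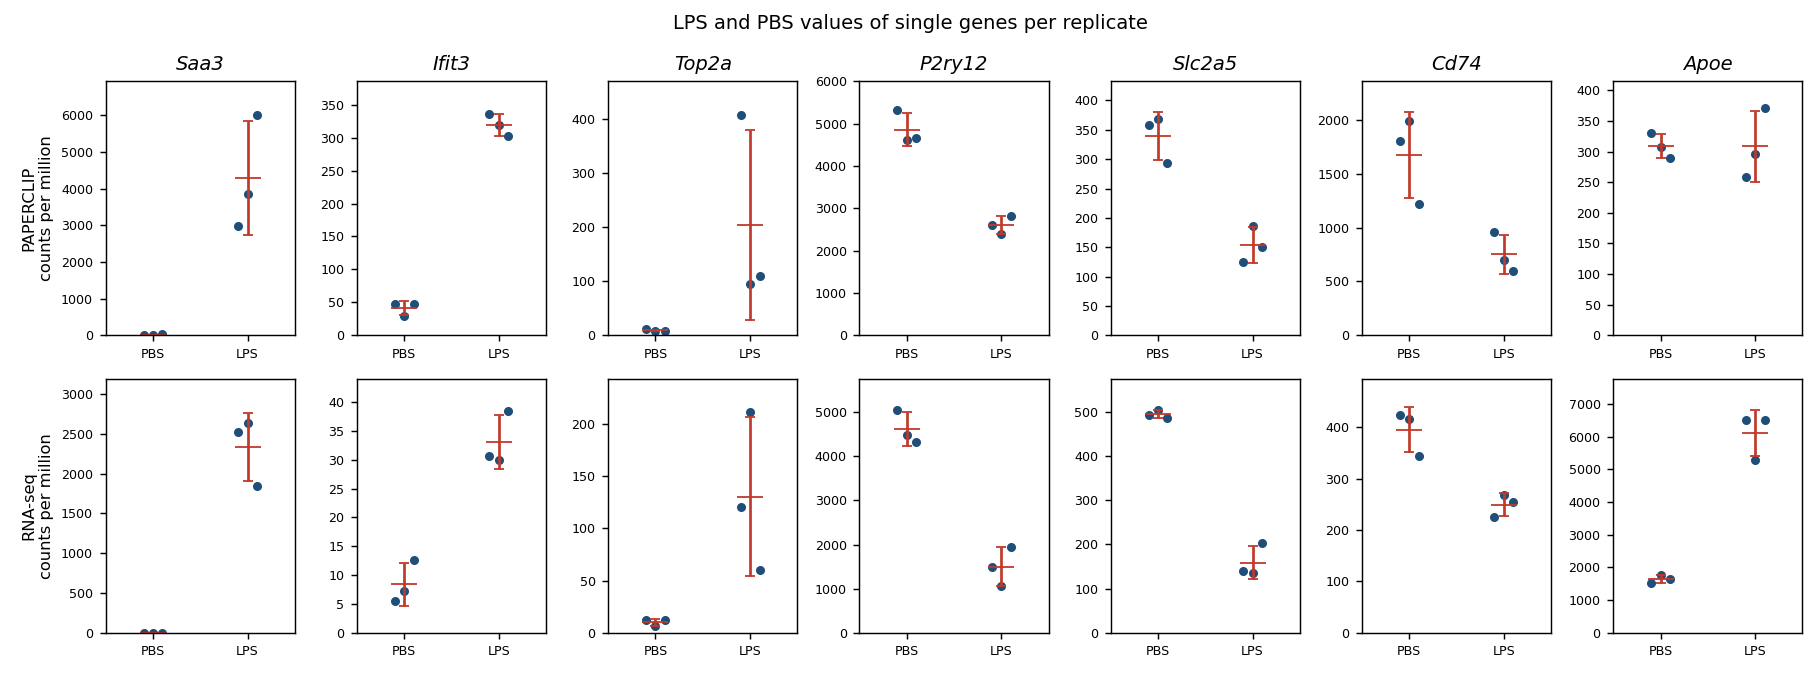
CPM per library of 7 genes in PBS and LPS groups, PAPERCLIP above and RNA-seq below, on axes from 0; blue points are libraries and red marks the mean and SD (n = 3). Saa3, Ifit3 and Top2a rose in both assays, and Apoe rose by 2.00 (log2) in RNA-seq against −0.02 in PAPERCLIP.

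The assays shared no library and were compared over the 5452 genes tested in both. In the fits without a replicate block, PAPERCLIP called 183 of them and RNA-seq 1597, with 165 called in both, all in the same direction. Of these 137 rose, against 27.3 for independent lists of 143 and 1040, and 28 fell, against 4.09 for lists of 40 and 557. Across genes, which are not independent replicates, the log2 changes had Pearson's r = 0.698 and Spearman's rho = 0.528. A direct test of the difference in LPS response, RNA-seq minus PAPERCLIP over 10165 genes, called only Apoe in edgeR without a block (difference 1.95, SE 0.22, adjusted p = 0.001), with 919 genes at an unadjusted p under 0.05 and 89 called by DESeq2. With the replicate within each assay as a block, 57 genes passed, 39 higher and 18 lower. Of simulated 4-fold differences this test, without the block, recovered 52% of higher and 53.1% of lower genes. The number was 6, 11, 2, 37 and 2 without PAPERCLIP PBS replicate 1, PBS replicate 2, LPS replicate 2, LPS replicate 3 and RNA-seq PBS replicate 3. In PAPERCLIP the Apoe change was −0.02 (SE 0.20, adjusted p = 0.976). The assays also differed in the mice and in how the cells were reached, tagged in whole brain or selected with beads, and the LPS dose is stated only for the RNA-seq mice.

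**Figure D3:**
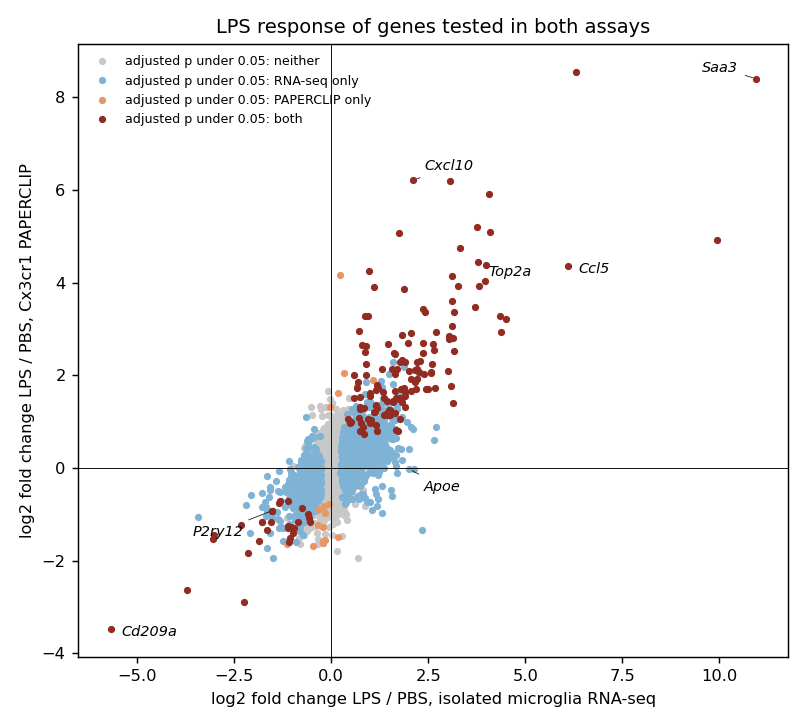
Log2 change after LPS in RNA-seq (horizontal) and PAPERCLIP (vertical) for the 5452 genes tested in both, each point a gene coloured by the assays that called it. The 165 genes called in both lie in the quadrants of equal sign, and Apoe lies at 2.00 in RNA-seq and −0.02 in PAPERCLIP.

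Araf encodes a RAF kinase and lies at chromosome X, 20797707 to 20860521 (GRCm38), where its span overlaps that of its neighbour Syn1. Its total level did not pass the test after LPS in either assay. In PAPERCLIP it averaged 46.9 ± 2.49 normalised CPM after LPS and 68.4 ± 24.3 after PBS (−0.56, SE 0.29, adjusted p = 0.38), and in RNA-seq 68.6 ± 4.12 and 74.8 ± 4.63 (−0.14, SE 0.11, adjusted p = 0.426). Among cell types it was lower in Camk2a than in Gad2 libraries (113 ± 0.956 against 198 ± 2.34; −0.81, SE 0.21, adjusted p = 0.00982), with an adjusted p of 0.0621, 0.0965, 0.144 and 0.145 without Gad2 replicate 1, Gad2 replicate 2, Camk2a replicate 1 and Camk2a replicate 2. The Gfap libraries differed from neuronal ones by −0.27 (SE 0.19, adjusted p = 0.235), which passed only with total counts as the scaling (−0.50, adjusted p = 0.0415), and the Cx3cr1 libraries from cortical ones by −0.36 (SE 0.28, adjusted p = 0.29). These values add all Araf isoforms and say nothing of a shift between them.

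The liver library had no replicate and entered no test. Alb, the serum albumin gene at chromosome 5, 90460870 to 90476602, took 6.07% of its counts (Clopper-Pearson 95% interval 5.93% to 6.21%). Pck1, a key enzyme of glucose synthesis, took 1.69% (1.62% to 1.77%), and Cps1, the first enzyme of the urea cycle, 1.53% (1.46% to 1.60%). All 19 hepatocyte list genes had counts and lay above every brain PAPERCLIP library, and together they took 13.99% of counts.

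In the Ptbp2-knockout cortex, Ptbp2 (chromosome 3, 119718741 to 119784647) still read 36.7, 28.5 and 26.3 CPM, a mean of 30.5 ± 5.51 (SD, n = 3). No wild-type embryonic cortex was analysed here and the deleted part is not given in the sources used here, so this level checks no label and no comparison was made. The related genes Ptbp1 and Ptbp3 averaged 41.2 ± 6.11 and 71.6 ± 5.70 CPM. Genes of young cortical neurons were abundant, with the microtubule proteins Tuba1a at 5028 ± 484, Dcx at 1692 ± 20.7 and Tubb3 at 1435 ± 51.8 CPM. Bcl11b, a transcription factor of deep cortical layers, averaged 166 ± 39.2 CPM, and Fabp7, a radial glial lipid carrier, 485 ± 57.5 CPM.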

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

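The tests of explanations in this part were chosen after the results they bear on were seen; the tests of differences in LPS response were planned. Apoe stood out because its LPS response differed between assays by 1.95 (log2, RNA-seq minus PAPERCLIP, edgeR adjusted p = 0.001). Its change was 2.00 in RNA-seq (95% interval 1.67 to 2.34), and the PAPERCLIP interval ended at 0.53, which argues against too few PAPERCLIP counts. Monocyte and border macrophage genes had a median RNA-seq change of 0.18 (SD 1.23, 11 genes), below that of Apoe by more than their SD. Members of this list went both ways, so its median cannot decide whether either cell type was a source. The 42 cytokine and interferon genes tested in RNA-seq had a median of 2.46 in PAPERCLIP with no filter and 0.89 in RNA-seq, which argues against a weaker response of all genes in PAPERCLIP. A difference between mRNA bound by the tagged protein and total mRNA, between tagged and bead-selected cells, or between mice may account for it and stays untested, and Apoe, abundant in astrocytes, could also reach the PAPERCLIP libraries from other cells.

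Neuronal genes were lower after LPS in PAPERCLIP, with a median log2 change of −1.56 (SD 0.50) over 12 pan-neuronal and excitatory genes. With libraries thinned to the same total count the median of the 8 genes left was −1.43. Thinning leaves the expected share of each gene unchanged, so it cannot decide whether the smaller yield of the PBS libraries played a part. Without PBS replicate 3 the median of the 12 genes was −0.40 (SD 0.48), so most of the difference rests on that library. Hepatocyte genes other than Ttr and Trf, which had counts in every brain PAPERCLIP library, took 0.224% of counts there and at most 0.00309% in any other PBS or LPS library (72.6 times). RNA from outside the microglia in that library may therefore be the source, while a loss of neuronal RNA from the tagged cells after LPS was not tested separately.

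Erythroid, mural and choroid plexus genes were lower after LPS in the isolated microglia, with a median log2 change of −1.78 over 19 genes. Oligodendrocyte genes had a median of −0.16 (SD 0.34, 8 genes) against −1.81 (SD 1.17, 7 genes) for mural genes, and astrocyte and endothelial genes lay between at −0.87 (SD 0.62, 12 genes) and −0.56 (SD 0.39, 12 genes). The other cell types thus moved apart, which argues against a larger share of microglia as the whole cause, though not as a part of it. With total counts as the only scaling the median of the 19 genes was −1.88, which argues against the scaling. Different cell types carried over in the dissociation, such as choroid plexus at 0.844% and 0.792% of counts in PBS replicates 1 and 2, may account for it, and a change in vessels or blood in the tissue after LPS stays open and untested.

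Several gene lists differed in LPS response between assays by camera, given as median log2 change in RNA-seq minus PAPERCLIP, and none held with an estimated correlation. The disease-associated microglia list was at 0.56 and complement at 0.0707 with a mean of 0.72. Cytokines and chemokines were at −2.33, interferon-stimulated genes at −0.67, NF-kB and acute-phase genes at −0.40, homeostatic microglia genes at −0.41 and dissociation and immediate early genes at −0.64. Erythroid genes were at −3.26, pan-neuronal genes at 0.91 (adjusted p = 0.0929 without PAPERCLIP PBS replicate 3) and 3 hepatocyte genes at 1.31 (adjusted p = 0.712 in the opposite direction without that library). In the knockout cortex, replicate 3 had 5.30% of its counts in a set of satellite-like genes. The set includes Gm10800, Gm10801 and Gm21738 among others, and was named after the values were seen. Gm10800 read 41432 CPM there and 17.7 and 7.26 CPM in replicates 1 and 2.

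Other splits of the libraries were counted. For LPS against PBS, 1 of 10 splits gave as many genes in PAPERCLIP (the real one, 201 genes; highest other 0) and 1 of 10 in RNA-seq (the real one, 2706; highest other 0), and 10 splits are too few for a share under 0.05. For the difference in LPS response, 7 of 100 splits, the real one included, gave as many genes as the real count of 1. The 6 others, with up to 733 genes, kept the RNA-seq groups whole and so carried the real LPS change there, a structure of the samples, and this share is no measure of chance.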

How the results depend on the processing

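The thinning of libraries and the knockout leave-one-out were chosen after seeing the data; the other alternatives were planned. Of 267 results for named genes, 206 kept their direction and side of the threshold in every alternative run. Over these genes, 3885 values were the same, 226 lost the threshold, 6 gained it and 7 reversed. Over lists, 991 were the same, 28 lost it and 1 reversed, and 64 of 69 lost it with an estimated correlation; the cause of these changes was not tested except where fewer counts or libraries were used. Few PAPERCLIP counts per gene, above all untreated, limit the comparisons that use those libraries.

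Thinned to the shallowest library, Camk2a against Gad2 called 551 genes and 3 lists, Gfap against neuronal 2271 genes and Cx3cr1 against cortical 2771, with fewer counts as the construction. There P2ry12 was at 0 in Camk2a against Gad2, and Araf at 0.12 in Gfap against neuronal and 0.33 in Cx3cr1 against cortical, all with adjusted p above the threshold. PBS against untreated called 214 genes with DESeq2, 313 and 1 list with no filter, and 169 with all 14 tagged brain libraries. LPS against PBS PAPERCLIP called 632 with no filter, 359 with all 14 libraries and 317 with the batch term. LPS RNA-seq called 1781 with DESeq2. The difference in LPS response called 89 with DESeq2 and 114 with no filter. With an estimated correlation, lists past the threshold fell to 1 for Camk2a against Gad2, 1 for Gfap, 0 for Cx3cr1, 3 for LPS PAPERCLIP, 0 for LPS RNA-seq and 0 for the difference, from 5, 11, 17, 10, 16 and 10 by camera. The correlation between assays was r = 0.706 and rho = 0.558 over genes of average log2 CPM of 5 or more in both, and r = 0.793 and rho = 0.763 over genes past the threshold in either. With no filter the median of all genes in Cx3cr1 against cortical was −0.79. For the cause of moves by tool or filter, the cause was not tested.

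With the replicate block, the paired fit of LPS against PBS PAPERCLIP called 423 genes and changed no call of a named gene or of a list by camera there; with an estimated correlation as well, 0 lists passed. List counts that it moved by over 1.5 times stand beside the main ones. In the difference in LPS response, which holds these libraries, the block within each assay gave 57 genes. The other libraries were not taken as paired (same-number correlations 0.0717, 0.0676 and 0.125 in RNA-seq, where LPS replicate 2 correlated best with PBS replicate 1 and replicate 3 differed in sex from 1 and 2 in both groups; 0.00231 to 0.0907 between untreated groups). Between PBS and untreated Cx3cr1 libraries, same-number correlations were 0.0485 for replicate 1 and 0.137 for replicate 2. In the comparisons of libraries not taken as paired, the block gave 140 genes for PBS against untreated and 2770 for LPS RNA-seq. Fits that left out a library had no block, in any comparison.

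Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 1026 to 2650 genes and 4 to 5 lists for Camk2a against Gad2, 4335 to 6384 and 10 to 13 for Gfap, 3569 to 4677 and 12 to 19 for Cx3cr1, 3 to 495 and 0 to 1 for PBS against untreated, 74 to 167 and 10 to 12 for LPS PAPERCLIP, 1845 to 2974 and 15 to 18 for LPS RNA-seq, and 1 to 37 and 8 to 12 for the difference in response. Ptbp2 in the knockout cortex averaged 27.4 to 32.6 CPM. Of called named genes, 33 of 41, 44 of 45, 46 of 48, 2 of 10, 15 of 38 and 59 of 65 kept their call without each library, in the order of the first 6 comparisons. Reversed without untreated replicate 2 were Pabpc1 (range −3.45 to 0.45) and Cx3cr1 (−0.60 to 0.33) in PBS against untreated. Reversed in the difference in response were Ptbp2 without PAPERCLIP PBS replicate 1 (−0.99 to 0.0649), Araf without PBS replicate 3 (lowest −0.0748) and the hepatocyte list without PBS replicate 3 (adjusted p from 0.000175 to 0.712). None of these had passed in the main result except the hepatocyte list.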

Other observations

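In the isolated microglia, gene groups of complement, metabolism and handling stress also differed between LPS and PBS libraries, from lists fixed before the data were examined. For the dissociation and immediate early genes, LPS and differences in handling during isolation cannot be told apart. Complement genes rose for 8 of 10 (8 rising and 1 falling adjusted over the list alone; camera adjusted p = 2.23e-10, and adjusted p = 0.0574 with an estimated correlation). Glycolysis genes rose for 10 and fell for 1 of 16, the same adjusted over the list alone (adjusted p = 0.00889, and adjusted p = 0.412 with an estimated correlation), with the pyruvate kinase Pkm at 0.89 (SE 0.15). Dissociation and immediate early genes rose for 2 and fell for 10 of 19, the same adjusted over the list alone (adjusted p = 8.22e-06, and adjusted p = 0.369 with an estimated correlation). The heat shock gene Hspa1b fell from 1307 ± 336 to 165 ± 39.1 normalised CPM (−2.99, SE 0.20) and the transcription factor Jun by 1.66 (SE 0.14), whereas the nuclear receptor Nr4a1 rose by 1.21 (SE 0.18).

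Sex-linked genes differed between libraries of a group. Xist, expressed from the inactive X chromosome, read 1154 and 1181 CPM in PBS replicates 1 and 2 of the microglial RNA-seq and 1405 and 1341 CPM in LPS replicates 1 and 2, against 1.14 and 1.60 CPM in replicate 3 of each. The Y-linked gene Ddx3y had no count in replicates 1 and 2 and read 160 and 123 CPM in replicate 3. Among PAPERCLIP libraries, Xist had no count in the Gfap and untreated Cx3cr1 libraries, and Ddx3y read 64.8 to 160 CPM in all 15.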
